A study of Rattus norvegicus with 16 samples.

How the data were processed

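Liver RNA of adult male Sprague-Dawley rats, 78 to 86 days old, was measured on 16 Agilent 2-colour arrays, 4 per group. The groups were C (dams given corn oil, pups left with their own mothers), CC (the same with litters fostered to another control dam), M (dams given 1.0 mg/kg/day of a mixture of organochlorine pesticides, polychlorinated biphenyls and methylmercury) and MM (the same dose, with litters fostered between exposed dams). For the M arrays the labels disagree, since 1 field names them as a control while their title and treatment give exposure, and they were taken as exposed. Dosing covered gestation and lactation until postnatal day 20, and per the labels each group held 8 pups, whose RNA was pooled in pairs, so that each array stands for 2 rats. Pools of 2 rats are the replicates, so the limma p-values of single features in the log ratio or liver channel measure the spread between pools. The p-values of the list test camera at its preset correlation set the genes of a list against all other genes. They do not measure that spread, and p-values of the reference channel compare hybridisations of the reference RNA. Siblings could not be told apart from unrelated pups. Per the labels' protocols, liver cRNA carried Cy5 and a universal rat reference RNA made from 14 rat cell lines carried Cy3 on every array, with no dye swap. Log ratios here are log2 of Cy5 over Cy3, so that a positive value means more signal in liver than in the reference.

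The deposited scanner files hold, per the file headers, median spot and local background intensity of both channels from Agilent Feature Extraction 11.0.1.1 and array design 028279. The same files hold, per the file headers, a log10 ratio of the processed red over the processed green signal, which the authors' scanner software had corrected for background and dye bias. The authors' deposited value table holds 1 value per probe and array on the log2 scale, as worked out here, and its making is not given in the sources used here. Set against each array's scanner values, it correlated at 0.989 to 0.996 with log2 ratios of loess-normalized signals without background subtraction, with slopes of 0.980 to 0.994, so its scale was taken as log2 and its direction as liver over reference. Its array medians ran from -0.04 to -0.03, and how it was centred stays unknown.

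Intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. The plan named mean spot signals, but the files carry medians only, so medians were used. Spots that the scanner software marked as non-uniform or population outliers were left out, 732 to 1138 per array, and replicate spots of a probe were averaged. Of 30367 probes, 18005 were given a current symbol by matching their accession, without version, to the RefSeq gene table of the GRCr8 assembly, and the rest kept the name in the file. The array was designed on an older build, so no coordinates are given. For each of 26913 names the brightest probe was kept, and a feature was tested if its liver signal was well above background on at least 3 of the 4 arrays of at least 1 group, which left 11084 features, 7372 of them with a symbol. Where several probes of a named gene differed in direction, the text says so.

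Precision is set by the number of arrays and by signal over background. Between 35.0% and 41.9% of probes were well above background in the liver channel (lowest in MM replicate 3, highest in M replicate 8) and between 61.6% and 66.1% in the reference channel. Median liver signal was 79 to 93 units per array, over a background of 69 to 73. The scanner software's median coefficient of variation between spots of a probe ran in the liver channel from 9.54% (C replicate 10) to 40.0% (MM replicate 3). It was highest in the first column of every slide row. In the reference channel it was 5.45% to 8.30% on the C and CC arrays and 9.42% to 12.5% on the M and MM arrays. Log ratios of any 2 arrays correlated at 0.949 to 0.992, and no arrays held identical liver signals.

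limma was fitted with 4 group means on all 16 arrays (12 residual degrees of freedom), and a feature was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were CC minus C, MM minus M, the difference between them (interaction), their mean, M minus C and MM minus CC. Before the data were examined, 24 pathway lists and 12 marker lists of cell types were fixed (1013 entries) and tested with camera at its preset correlation of 0.01, adjusted over the 36 lists. The rule for named genes was fixed at the same time. It takes up to 10 called genes per direction with the largest change and no overlap between the groups' arrays, or else the 5 with the lowest p, given as values only, then up to 4 members with the lowest p from each list that was called or held a called member, and a set of liver genes always given where measured. A few genes that this rule or the tests of gene pairs and outlying arrays take up are not reported here, but they stay in the counts of what was tested. Standard errors (SE) come from the fit. The fits were tested on simulated data made from the real means and spreads. With 100 features changed by 1 log2 unit each, 92 were recovered in CC minus C, 97 in MM minus M, 94 in M minus C and 93 in MM minus CC. At 0.5 log2 units, 43, 54, 50 and 46 of 100 were recovered. With the real deviations from the group means in place of simulated ones, 96, 92, 92 and 92 of 100 were recovered at 1 log2 unit and 45, 42, 43 and 35 at 0.5.

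All C and CC arrays lay on slide 1 and all M and MM arrays on slide 2. The cross-fostering contrasts therefore stay within a slide, whereas M minus C and MM minus CC also compare the slides. The reference channel was tested between slides for that reason, after quantile normalization of Cy3 intensities, and changes in the liver channel alone or in the reference alone are given for the leading genes of the exposure contrasts and for the calls as a whole. Each slide held 2 rows of 4 arrays, and every row held 2 arrays of each of its groups, so row could be taken up as a block. The main fit does not take it up, so its standard errors and p-values include differences between rows. CC and MM share the sample numbers 1 to 4. Deviations from the group means correlated at 0.56, 0.16, 0.58 and 0.19 between arrays of the same number, so the numbers were taken to pair these arrays. Same-numbered arrays also share the row of the slide, and the highest correlations with another number were 0.45, 0.23, 0.33 and 0.16.

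Alternatives tried for each comparison were no background subtraction, the scanner's log ratio, quantile normalization of average intensity between arrays, the liver channel alone, the deposited table, no filter and a stricter filter, all probes or their mean, a fit of the compared groups only, array weights, a robust prior, the slide row as a block, other thresholds, the pairing as a block and leaving out each array in turn. For a probe not well above background on any array of a group, lower bounds of the fold were computed in the liver channel after loess and between-array normalization of average intensity. They are not given, because they exceeded the differences in the quantile-normalized liver channel and rest partly on arrays near background.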

Results

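The series asks how cross-fostering, the adoption of a litter at birth, and exposure to an environmental mixture before weaning bear on gene expression in the adult liver. There were 16 arrays of adult male rat liver, 4 each from control (C), cross-fostered control (CC), mixture-exposed (M) and cross-fostered mixture-exposed (MM) animals, each array a pool of 2 rats read against a common reference RNA. Values below are log2 ratios of liver over reference, and 11084 features were bright enough in liver to be tested.

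Cross-fostering of control litters was examined by CC minus C. In control rats, no single gene separated fostered from non-fostered livers past the threshold. Genes of nuclear-encoded oxidative phosphorylation, which make up the mitochondrial respiratory chain, were shifted downward in CC as a list, with 48 of 65 members below 0 and a median change of -0.07 (camera adjusted p = 0.000546). All 11 tested markers of liver sinusoidal endothelium were higher in CC, with a median of 0.10 (camera adjusted p = 0.000546). Neither shift held with an estimated correlation between genes (adjusted p = 0.487 for both lists). Within the first slide row the endothelial median was 0.014 (camera adjusted p = 0.562) and within the second 0.14 (7.79e-06), and the oxidative phosphorylation medians were -0.084 (0.000269) and -0.071 (0.231). The count of 2 lists became 5 without CC replicate 1, 4 without CC replicate 2, 6 without C replicate 10 and 5 without C replicate 12.

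Among oxidative phosphorylation genes, the complex I subunit Ndufs7 differed by -0.22 ± 0.11 (SE, n = 4 per group), the complex III subunit Uqcrq by -0.31 ± 0.16 and the complex IV subunit Cox5b by -0.22 ± 0.12, whereas the complex I subunit Ndufa10 went the other way at 0.20 ± 0.10. Among endothelial markers, the largest values belonged to Eng (endoglin, 0.30 ± 0.15) and Kdr, a VEGF receptor (0.23 ± 0.19). Without 1 array, values moved by over 1.5 times for Cox5b (-0.11 without C replicate 11), for Ndufs7 and Ndufa10 (-0.13 and 0.13 without CC replicate 4) and for Kdr (0.095 without C replicate 11, 0.12 without 12, 0.41 without 10 and 0.15 without CC replicate 2). Adjusted over the list alone, 0 members of either list passed. Of single genes, the lowest p belonged to Ednra, the endothelin A receptor (0.56 ± 0.14), followed by the prelamin protease Zmpste24 (-0.39 ± 0.11) and the aldo-keto reductase Akr1c1 (-0.48 ± 0.14), and the 4 values of each group did not overlap for these 3 genes. The groups did not overlap in 95 of all features (0.857%), where chance gives 2.86%. For genes picked by their low p, a lack of overlap adds no support. The apolipoprotein gene Apoc1 differed by 0.39 ± 0.12. Prima1 and Fxyd7 were not well above background on any CC array and were so on 1 and 2 of the 4 C arrays, and Trpt1 was on no C array and on 3 CC arrays, so no fold is given for them (adjusted p = 1.00 in the limma fit). Closely related members of the Akr1c family may hybridise to the same probe, so their values are uncertain as to the member.

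limma called 0 of 11084 features in CC minus C, 105 had an unadjusted p under 0.05 where chance gives 554, and the rotation test fry, which asks whether a list moved on balance, called 0 lists. That limma fit counts the slide row as spread between pools, and with the row as a block 288 features had an unadjusted p under 0.05. The scanner's own log ratio gave 1 call, Scmh1, a Polycomb gene named after its value was seen (-0.62, adjusted p = 0.0481, against -0.09 in the loess values). For 98.9% of features, the 95% interval of the difference lay within a 2-fold change.

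Cross-fostering of exposed litters was examined by MM minus M. In the fostered exposed animals, genes of interferon response and antigen presentation were lower as a list, with 28 of 33 members below 0 and a median of -0.15 (camera adjusted p = 7.27e-06). Cholesterol biosynthesis genes were higher, with 18 of 25 members above 0 and a median of 0.14 (adjusted p = 0.000219). Ribosomal protein genes (60 of 72 above 0, median 0.08, adjusted p = 7.96e-05) and cell cycle genes (20 of 22, median 0.11, adjusted p = 0.00111) were also higher. None of these list calls, nor the other 4 of this contrast, held with an estimated correlation, the smallest adjusted p then being 0.523. In the liver channel alone the interferon and cholesterol lists stayed called (medians -0.13 and 0.15, adjusted p = 7.68e-06 and 1.59e-05). There the ribosomal median was 0.0084 (adjusted p = 0.420) and the cell cycle median 0.014 (adjusted p = 0.766).

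In the interferon list, Psmb8, a subunit of the immunoproteasome, differed by -0.32 ± 0.14 (SE, n = 4 per group), the RNA sensor Dhx58 by -0.20 ± 0.09 and the 2'-5'-oligoadenylate synthetase Oas1a by -0.64 ± 0.37. In the cholesterol list, Hmgcs1, which makes HMG-CoA, differed by 0.51 ± 0.25, Acat2 by 0.34 ± 0.13 and Mvd by 0.26 ± 0.14. The list of PPARalpha targets and fatty acid oxidation was lower (29 of 38 below 0, median -0.09, adjusted p = 0.0108), with Cpt1a, the carnitine palmitoyltransferase of the liver, at -0.49 ± 0.27. With an estimated correlation the adjusted p of this list was 0.523. In the ribosomal list, the largest value was that of Rpl36 (0.26 ± 0.13), and in the cell cycle list that of the mitotic kinase Plk1 (0.22 ± 0.11). Single arrays moved some of these values by over 1.5 times, Cpt1a to -0.31 and Plk1 to 0.12 without M replicate 8, Oas1a to -0.38 without MM replicate 2 and Rpl36 to 0.14 without MM replicate 3.

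Markers of erythroid cells were higher in MM (7 of 8 above 0, median 0.15, adjusted p = 0.00282, and adjusted p = 0.523 with an estimated correlation), led by the beta-globin gene Hbb-b1 (0.50 ± 0.21) and the globin chaperone Ahsp (0.37 ± 0.18, and 0.15 without MM replicate 2). All 4 tested B cell markers lay above 0 (median 0.17, adjusted p = 0.0415, and 0.125 in the liver channel alone). Hepatocyte markers had a median of 0.09 in the log ratio (11 of 15 above 0, adjusted p = 0.0415) but -0.09 in the liver channel alone, with the reference channel at -0.10. These 3 shifts were measured in the same arrays as the pathway shifts, and none held with an estimated correlation (adjusted p = 0.523). Adjusted over the list alone, 0 members of any of the 8 called lists passed. The single genes with the lowest p were Fgl1, a secreted fibrinogen-like protein (-0.72 ± 0.18), Ednra (-0.49 ± 0.14) and the small GTPase Rab17 (-0.63 ± 0.19) on the lower side, and Akr1c1 (0.43 ± 0.14) on the higher side. The transcription factor gene Elk3 was not well above background on any M array and was so on 3 MM arrays, and no fold is given (adjusted p = 1.00).

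limma called 0 features in MM minus M, 197 had an unadjusted p under 0.05 against 554 from chance, and fry called 0 lists. Once the slide row was a block in the limma fit, 403 features had an unadjusted p under 0.05. With the row of the slide as a block, which leaves the medians as they are, 6 of the 8 list calls stayed. Within the first row the ribosomal median was -0.0055 and within the second 0.18, and the interferon median was -0.26 in the first row and -0.04 in the second. In the same order the medians were 0.070 and 0.30 for cholesterol, -0.041 and -0.091 for PPARalpha, -0.015 and 0.19 for cell cycle, 0.35 and 0.093 for erythroid, 0.15 and 0.13 for B cell and 0.17 and 0.091 for hepatocyte genes. The count of 8 lists became 5 without MM replicate 2 or 3 or M replicate 7 or 8.

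The interaction asks whether fostering differed in its effect between exposed and control litters. The genes that led both contrasts went in opposite directions in them, which is what the plot of log ratios by group shows for Ednra and Akr1c1. Ednra was higher in CC than in C and lower in MM than in M, a difference between the contrasts of -1.05 ± 0.20 (limma adjusted p = 0.854, the smallest of all features). Akr1c1 went the other way, with a difference of 0.90 ± 0.19, as did its relatives Akr1c2 (1.85 ± 0.58) and Akr1c13 (1.53 ± 0.49), all with an adjusted p of 0.999.

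**Figure D1:**
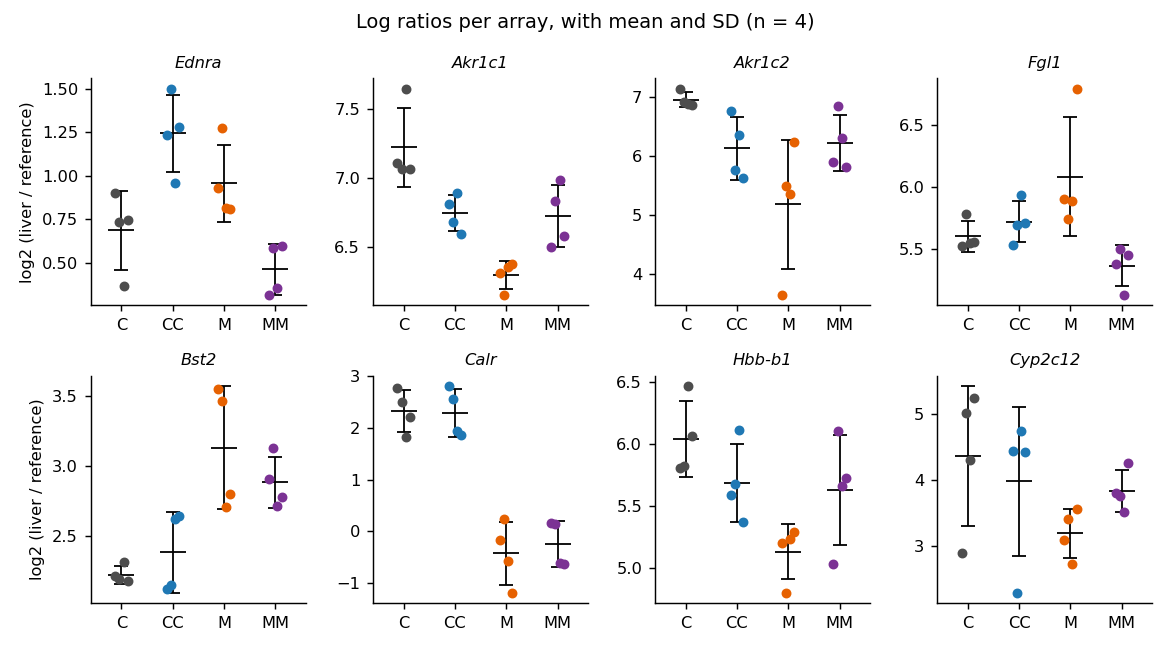
Log2 ratio of liver over reference for 8 genes, 1 point per array (n = 4 per group), with bars for the group mean and SD, in the groups C, CC, M and MM. Ednra is higher in CC than in C and lower in MM than in M, and Calr is at most 0.23 on the M and MM arrays and at least 1.81 on the C and CC arrays.

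In the interaction 9 lists were called, none of which held with an estimated correlation (smallest adjusted p = 0.615). The 9 became 1 without C replicate 11, 2 without C replicate 9 or MM replicate 2, 4 without CC replicate 4 and 5 without M replicate 8. The list of liver sinusoidal endothelium markers had a median difference of -0.11 (8 of 11 below 0, adjusted p = 0.00466), with Eng at -0.77 ± 0.22 the 1 member of all lists that passed when adjusted over the list alone. Kupffer cell and macrophage markers were lower as well (13 of 17 below 0, median -0.12, adjusted p = 0.00639), led by the metal transporter Slc11a1 (-0.44 ± 0.15) and the complement gene C1qc (-0.64 ± 0.27). Slc11a1 was well above background on 2, 4, 4 and 3 arrays of C, CC, M and MM. Cholesterol biosynthesis (19 of 25 above 0, median 0.23, adjusted p = 0.00203), ribosomal proteins (56 of 72, median 0.14, adjusted p = 0.000352), oxidative phosphorylation (43 of 65, median 0.07, adjusted p = 0.0273) and erythroid markers (7 of 8, median 0.20, adjusted p = 0.0273) were higher. Interferon genes (24 of 33 below 0, median -0.14, adjusted p = 0.00308), glucocorticoid-responsive genes (24 of 28, median -0.09, adjusted p = 0.0273) and PPARalpha targets (26 of 38, median -0.08, adjusted p = 0.0356) were lower. The glucocorticoid list was led by the transcription factor gene Klf9 (-0.47 ± 0.22). With the slide row as a block 6 of the 9 calls held, and in the liver channel alone 7 held, while those of ribosomal proteins (median 0.024, adjusted p = 0.780) and oxidative phosphorylation (0.04, adjusted p = 0.187) were lost. Within the first slide row the ribosomal median was -0.08 (camera adjusted p = 0.0111), opposite to that of all arrays, and within the second row it was 0.35. Kupffer cell medians were -0.18 in the first row and -0.010 in the second (adjusted p = 0.484), and interferon medians -0.17 and -0.018 (adjusted p = 0.443). In the same order the medians were 0.22 and 0.27 for cholesterol, -0.092 and -0.12 for endothelial, 0.063 and 0.11 for oxidative phosphorylation, 0.24 and 0.16 for erythroid, -0.059 and -0.20 for glucocorticoid-responsive and -0.028 and -0.15 for PPARalpha genes.

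**Figure D2:**
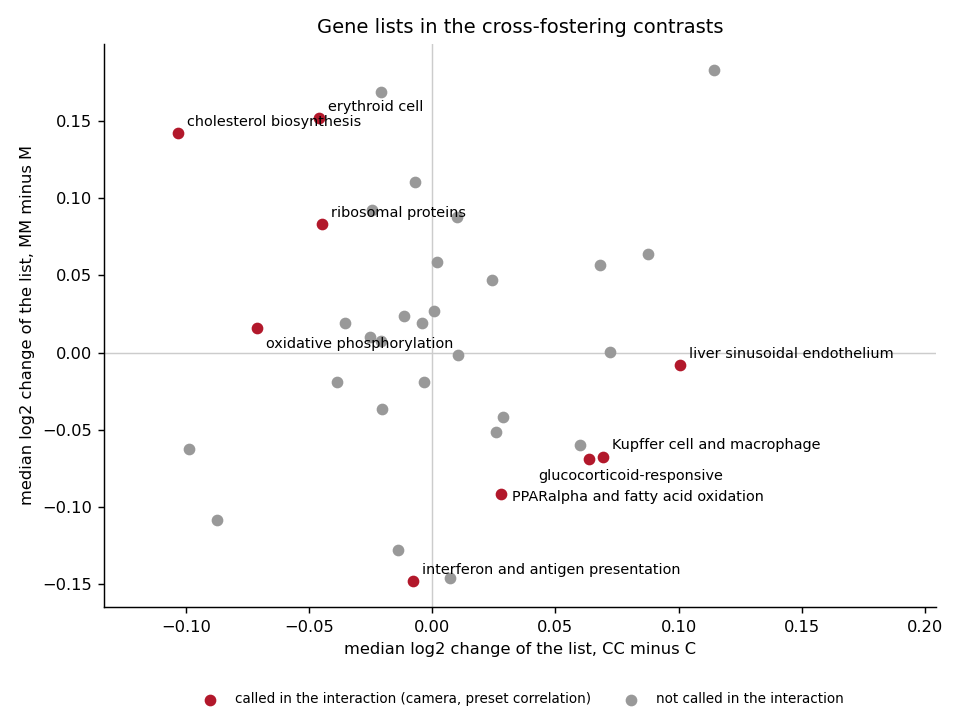
Median log2 change of each of the 36 gene lists, CC minus C on the horizontal axis and MM minus M on the vertical axis, 1 point per list, with the 9 lists called in the interaction in red and named. Cholesterol biosynthesis lies at -0.10 in control rats and at 0.14 in exposed rats, and interferon genes lie at -0.15 in exposed rats.

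In the mean of both fostering contrasts, limma again called 0 features (106 at an unadjusted p under 0.05, and 0 without overlap of the groups on both slides). Of the 4 lists called, none held with an estimated correlation (smallest adjusted p = 0.621). Fatty acid synthesis genes were lower (17 of 21 below 0, median -0.08, adjusted p = 0.0169), with malic enzyme (Me1) at -0.24 ± 0.17, but the median was -0.17 in the first slide row (adjusted p = 7.54e-05) and 0.042 in the second (adjusted p = 0.571). Interferon genes (29 of 33 below 0, median -0.06, adjusted p = 0.000805) and oxidative phosphorylation genes (57 of 65, median -0.03, adjusted p = 0.0306) were lower, and cell cycle genes were higher (20 of 22 above 0, median 0.05, adjusted p = 0.000805) in the log ratio, although their median in the liver channel alone was -0.0044. The other 3 lists stayed called in that channel. Medians in the first and second rows were -0.13 and -0.028 for interferon, -0.054 and -0.0099 for oxidative phosphorylation and 0.020 and 0.077 for cell cycle genes. The count of lists became 0 without CC replicate 1, 2 without M replicate 6, and 7 without CC replicate 2 or 4 or MM replicate 1. The fold changes of the 2 contrasts, which share no array, correlated at -0.188 across genes (Spearman -0.230), with the same sign in 41.3% of features, where genes are not independent replicates.

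Several of the genes picked in advance for their roles in the liver differed little in the mean fostering effect. The glucocorticoid receptor gene Nr3c1 stood at 0.09 ± 0.10, its target Fkbp5 at -0.03 ± 0.13, the gluconeogenic gene Pck1 at -0.08 ± 0.11, the male-specific Cyp2c11 at 0.06 ± 0.08 and the growth factor gene Igf1 at 0.05 ± 0.09. Nr3c1 was well above background on only 2, 3, 2 and 1 arrays of C, CC, M and MM, so its value says little. The clock output gene Dbp (0.44 ± 0.38), the bile acid enzyme gene Cyp7a1 (-0.17 ± 0.46) and the desaturase gene Scd (-0.17 ± 0.32) varied more between pools, and leaving out 1 array took Dbp to 0.25 (without CC replicate 4) or 0.27 (C replicate 10), Cyp7a1 to between -0.49 and 0.06 and Scd to between -0.38 and 0.06. A mean can hide changes that differ between the contrasts. In CC minus C, Dbp stood at 0.82, the female-biased Cyp2c12 at -0.38 and Cyp2b2 at 0.22. Their interactions were -0.76, 1.02 and -0.87, and no feature passed in either. Without CC replicate 2 the interaction of Cyp2c12 was 0.46, and on the other probe of Cyp2b2 it was -0.26. Cyp1a1 and Dnmt1 were not well above background on any array, and Cyp2b1 had no probe under that symbol.

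Exposure without fostering was examined by M minus C. The log ratio of Calr, which encodes the chaperone calreticulin, fell by 2.75 ± 0.31 (SE, n = 4 per group), that of Acin1 by 2.32 ± 0.20 and that of the heat shock protein gene Hsp90ab1 by 1.45 ± 0.19, but most of each change lay in the reference RNA, where the signal was higher on slide 2 by 1.97, 1.75 and 1.49. In the liver channel these genes differed by -0.70, -0.49 and 0.15, and the other probe of Acin1 stood at -1.09 and that of Hsp90ab1 at -0.17. The log ratio of Akr1c2 fell by 1.77 ± 0.41 and that of Hbb-b1 by 0.91 ± 0.21, and here the liver channel differed by more than the reference (-1.98 against -0.42, and -1.03 against -0.10). On the higher side, the interferon-induced membrane protein gene Bst2 rose by 0.91 ± 0.18 (adjusted p = 0.00960), with 0.84 in the liver channel and -0.15 in the reference.

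limma called 466 features, 176 higher and 290 lower, of which 191 changed by at least 1.5-fold. Of the 466, 435 (93.3%) also differed between slides in the reference channel, against 62.7% of all features. In 433 of the 466 the reference moved in the direction that yields the call. Calls were made on the log ratio, of which the reference is a part, so such a match is favoured by the selection. The same holds for the share that follows, and neither was taken over all features. The median share of the change that lay in the reference was 66.4% (quartiles 47.1% and 81.3%). This share is taken of the liver change minus the reference change, each channel normalized on its own, which need not equal the change of the log ratio. In the liver channel alone 1 feature passed, the olfactory receptor gene Or5h25d (0.60 ± 0.08), whose reference signal differed by 0.61 in the same direction. Its log ratio still differed by 0.67 (limma adjusted p = 0.000629), so the separately normalized channels do not subtract to the log ratio. Or5h25d was well above background on only 2 C arrays. With the slide row as a block, 89 features passed in the liver channel, 68 higher and 21 lower, against the 176 and 290 of the log ratio, and 37 of them were among the 466. Per the labels a universal reference RNA was put on every array, but whether 1 lot or labelling served both slides is not given. Between slides the reference channel differed in 6952 features (3270 higher and 3682 lower on slide 2), and the liver channel in 222 (167 higher and 55 lower). The sizes were closer than these counts, with a median absolute difference of 0.090 log2 units in the reference and 0.072 in the liver channel. Neither fit took up the slide row. Exposure and slide cannot be told apart in this design.

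**Figure D3:**
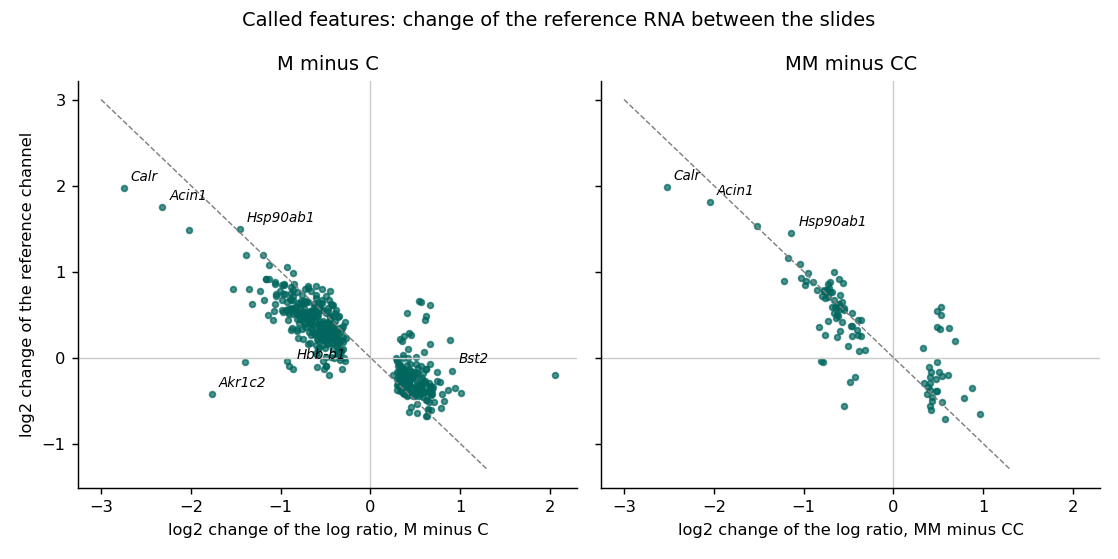
Change of the reference channel (vertical axis, log2) against the change of the log ratio (horizontal axis, log2) for the 466 features called in M minus C (left) and the 98 called in MM minus CC (right), 1 point per feature. On the dashed line the whole change lies in the reference. In M minus C the reference change is 1.97 for Calr, 1.75 for Acin1, -0.42 for Akr1c2 and -0.10 for Hbb-b1.

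By list, 4 were called, and none held with an estimated correlation (adjusted p = 0.780 for each). Ribosomal protein genes were lower in M (67 of 72 below 0, median -0.20, camera adjusted p = 3.59e-05), with 3 members past the threshold, among them Rpl28 (-0.34 ± 0.08) and Rpl36 (-0.53 ± 0.13), but in the liver channel the list median was -0.059 (adjusted p = 0.230) and these genes stood at -0.18 and -0.07. In the interferon list 3 of 33 members rose and 0 fell, namely Psmb8 (0.80 ± 0.14), the class II chaperone gene RT1-DMb (0.39 ± 0.10) and the peptide transporter gene Tap1 (0.43 ± 0.11), with a list median of 0.11 (adjusted p = 0.0497). These 3 genes differed by 0.38, 0.22 and 0.18 in the liver channel, and Tap1 was well above background on only 2 C and 3 M arrays. The list was not called with the slide row as a block (adjusted p = 0.0675), and its median was -0.031 within the first row and 0.083 within the second, whereas in the liver channel it stayed called (median 0.12, adjusted p = 0.00131). Of 65 oxidative phosphorylation genes 53 lay below 0 (median -0.12, adjusted p = 0.0497), and Ndufb10 fell (-0.42 ± 0.11) while the ATP synthase gene Atp5f1b rose (0.60 ± 0.12). The list median in the liver channel was -0.030 (adjusted p = 0.169), with Ndufb10 at -0.32 and Atp5f1b at 0.33. Hepatocyte markers were lower in the log ratio (14 of 15 below 0, median -0.26, adjusted p = 0.0218), with transferrin (Tf, -0.58 ± 0.16) and Apoa2 (-0.45 ± 0.12) past the threshold, but their median was 0.04 in the liver channel and 0.13 in the reference, with Tf at -0.15 and Apoa2 at 0.05 in the liver channel. fry called 5 lists, among them oxidative phosphorylation and hepatocyte markers but neither ribosomal proteins (adjusted p = 0.147) nor interferon genes (adjusted p = 0.354). Adjusted over the list alone, 7 ribosomal, 4 interferon, 3 oxidative phosphorylation and 4 hepatocyte genes passed.

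Of markers of other cells, single genes passed. The erythroid gene Hbb-b1 fell and 7 of the 8 erythroid markers lay below 0 (median -0.34, list adjusted p = 0.0959), the endothelial gene Eng rose by 0.66 ± 0.15, the macrophage gene Slc11a1 rose by 0.49 ± 0.11 and the stellate cell receptor gene Pdgfrb fell by 0.48 ± 0.09. Eng differed by 0.44, Slc11a1 by 0.30 and Pdgfrb by -0.29 in the liver channel, and Slc11a1 was well above background on 2 C and 4 M arrays. The P450 oxidoreductase gene Por, which serves all microsomal P450 enzymes, rose by 0.94 ± 0.25 (0.59 in the liver channel), and the male-biased Cyp2c13 fell by 0.77 ± 0.18 (-0.22 in the liver channel and 0.50 in the reference). The beta-oxidation gene Hadha stood at -1.35 ± 0.19 on its brightest probe (-0.51 in the liver channel) and at 0.55 on its other probe. Among genes fixed for their roles in the liver, the female-biased Cyp2c12 stood at -1.16 ± 0.50 (adjusted p = 0.242), Dbp at 1.31 ± 0.54 (adjusted p = 0.213), Cyp1a2 at -0.20 ± 0.17, Cyp2b2 at 0.52 ± 0.38 and Cyp3a23-3a1 at -0.28 ± 0.17, none past the threshold. The other probe of Cyp2b2 stood at 0.0029. Leaving out 1 array took Cyp1a2 to between -0.36 and -0.07, Cyp2b2 to between 0.17 and 0.80 and Cyp3a23-3a1 to -0.14 (without C replicate 10).

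The count of 466 became 268 with the C and M arrays fitted alone, 1202 with the slide row as a block, 184 within the first row and 4 within the second. It fell below 466 by over 1.5 times without C replicate 9 (301), 10 (287), 11 (279) or 12 (288), and without M replicate 5 (295), 6 (278) or 8 (213). The 4 lists became 2 without C replicate 11 or M replicate 8 and 1 without M replicate 7. Medians in the first and second rows were -0.12 and -0.28 for ribosomal, -0.093 and -0.14 for oxidative phosphorylation and -0.25 and -0.31 for hepatocyte genes.

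Exposure with fostering was examined by MM minus CC. The log ratio of Calr fell by 2.52 ± 0.31 (SE, n = 4 per group), that of Acin1 by 2.05 ± 0.20, that of Reep3 by 1.22 ± 0.23 and that of the linker histone gene H1f4 by 1.17 ± 0.12, with reference changes of 1.98, 1.81, 0.88 and 1.16. The other probe of Acin1 stood at -0.78 and that of Reep3 at -0.12. On the higher side stood Marf1 (0.96 ± 0.14) and the histone mRNA binding protein gene Slbp (0.79 ± 0.12), with liver-channel values of 0.29 and 0.31. The P450 gene Cyp3a23-3a1, a target of the pregnane X receptor, stood at -0.65 ± 0.17 without overlap between the groups (-0.38 in the liver channel, adjusted p = 0.118). Of all features, 6.55% did not overlap, where chance gives 2.86%.

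limma called 98 features, 32 higher and 66 lower, and 52 of them changed by at least 1.5-fold. Of the 98, 94 (95.9%) also differed between slides in the reference, and in 85 of the 98 the reference moved in the direction that yields the call. The median share in the reference was 85.8% (quartiles 55.3% and 101.7%). As in M minus C, selection on the log ratio favours a matching direction and a high share. In the liver channel alone 3 features passed, Dot1l (0.61), Or5h25d (0.55) and an unnamed transcript (-0.54), and in each the reference differed in the same direction (0.55, 0.59 and -0.57). Their log ratios still differed by 0.48, 0.53 and -0.55 (limma adjusted p = 0.0202, 0.00977 and 0.0303), since the channels were normalized separately. With the slide row as a block, 46 features passed in the liver channel, 26 higher and 20 lower, against the 32 and 66 of the log ratio, and 14 of them were among the 98. Of the calls, 83 were shared with M minus C, all in the same direction, where independent lists would share 0.508 higher and 1.73 lower ones. These comparisons share no array but share both slides, and 82 of the 83 also differed in the reference. Prima1 was among the calls (adjusted p = 0.0363), but it was not well above background on any CC array, so no fold is given, and its reference signal was higher by 0.49.

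Of the lists, 5 were called, and none held with an estimated correlation (smallest adjusted p = 0.253) or in the liver channel alone. PPARalpha targets and fatty acid oxidation genes were lower (32 of 38 below 0, median -0.17, camera adjusted p = 0.00273), with Cyp4a3 at -0.48 ± 0.14 and the thioesterase gene Acot4 at -0.69 ± 0.23. With an estimated correlation the adjusted p of this list was 0.670, and its median in the liver channel was -0.094 (adjusted p = 0.167), with Cyp4a3 at -0.24 and Acot4 at -0.34. The 1 member past the threshold was Hadha, at -0.89 ± 0.19 on its brightest probe (0.06 in the liver channel) and 0.27 on its other. Acute phase genes (24 of 27 below 0, median -0.20, adjusted p = 0.00441) and targets of CAR and PXR, the nuclear receptors for foreign compounds (23 of 27 below 0, median -0.21, adjusted p = 0.0409), were lower, with Orm1 at -0.36 ± 0.13, Crp at -0.52 ± 0.22 and Cyp2c6v1 at -0.44 ± 0.19. With an estimated correlation the adjusted p was 0.697 for acute phase genes and 0.818 for CAR and PXR targets. Their medians in the liver channel were -0.069 (adjusted p = 0.405) and -0.038 (adjusted p = 0.836), with Orm1 at -0.16, Crp at -0.14 and Cyp2c6v1 at -0.30. Without MM replicate 3 the log ratio of Cyp2c6v1 was -0.27. All 9 male-biased liver genes lay below 0 (median -0.25, adjusted p = 0.00441, and 0.253 as the adjusted p with an estimated correlation), but their median was 0.05 in the liver channel. Immediate early genes were higher (17 of 24 above 0, median 0.09, adjusted p = 0.0409), led by Ccn1 (0.53 ± 0.14) and Nr4a2 (0.34 ± 0.11). With an estimated correlation their adjusted p was 0.818, and in the liver channel their median was 0.019 (adjusted p = 0.992), with Ccn1 at 0.08 and Nr4a2 at 0.10. Their median was 0.28 in the first slide row (adjusted p = 3.06e-05) and -0.057 in the second (adjusted p = 0.920). fry called 1 list, the male-biased genes. Adjusted over the list alone, 1 PPARalpha gene and 1 immediate early gene passed, and none of the CAR and PXR, acute phase or male-biased lists.

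The count of 98 became 14 with the CC and MM arrays fitted alone, 131 with the sample number as a replicate block (20 higher and 111 lower, 61 of them among the 98), 421 with the slide row as a block, 65 within the first row and 1 within the second. It fell below 98 by over 1.5 times without CC replicate 1 (43), 2 (35) or 3 (53) and without MM replicate 2 (46) or 4 (31), and with the replicate block the immediate early genes were no longer called (adjusted p = 0.0502), nor were Prima1, Dapk3, Mtnr1a and Krt8, while Acot4 passed (adjusted p = 0.0454). The 5 lists became 3 without MM replicate 2, and medians in the first and second rows were -0.064 and -0.25 for PPARalpha, -0.087 and -0.30 for acute phase, -0.16 and -0.12 for CAR and PXR and -0.37 and -0.34 for male-biased genes.

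Each slide held 2 rows of arrays, with 2 arrays of each of its groups in each row. In the liver channel 5025 features (45.3%) differed between the rows, 2388 higher and 2637 lower in the second, against 155 (1.40%) in the reference channel. Across genes, which are not independent replicates, the row effects of slide 1 and slide 2 correlated at 0.765 in the liver channel and at 0.198 in the reference. Within slide 1 there were 2047 such features and within slide 2 3601. Among the 8 largest row effects in each direction were those of Crym, a thyroid hormone binding protein gene (1.35 ± 0.29 higher in the second row), the transcription factor gene Cebpb (0.98 ± 0.20) and the peroxisomal Pex11a (0.92 ± 0.07), and on the lower side Tor1aip1 (-0.95 ± 0.10), the glycosyltransferase gene Alg11 (-0.94 ± 0.14) and the mitochondrial iron carrier gene Slc25a28 (-0.91 ± 0.08). No list was called between rows (camera adjusted p = 0.941 at the smallest).

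**Figure D4:**
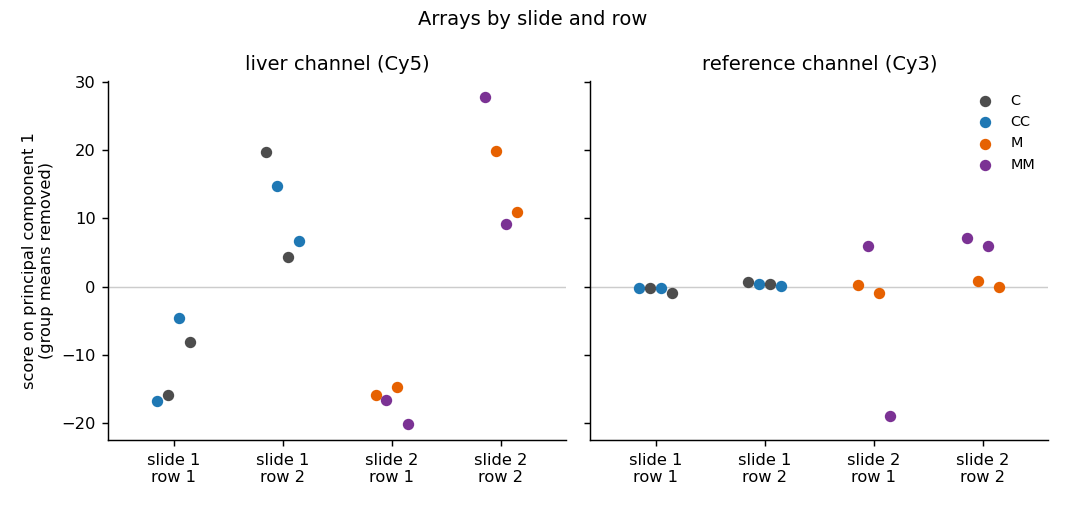
Score of each array on the first principal component of deviations from the group means, for the liver channel (left) and the reference channel (right), by slide and row and coloured by group. Liver scores run from -20.2 to -4.61 in the first rows and from 4.32 to 27.8 in the second rows, and the reference score of MM replicate 2 is -19.0.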

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

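Of the tests below, the share of a change that lies in the reference, the use of the liver channel alone and of the estimated correlation to weigh an explanation, the position effect on both channels, the lists in the liver channel, with the slide row as a block or within a row, and the liver channel with the row as a block were chosen after the result was seen, whereas the features in the liver channel alone, the reference channel between slides, the lists with an estimated correlation, the splits of the arrays, the spike-in test and the features with the slide row as a block were chosen before.

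The cross-fostering contrasts differed between exposed and control rats in 9 gene lists by the interaction test. The median differences were 0.23 for cholesterol biosynthesis, 0.20 for erythroid markers, 0.14 for ribosomal proteins and 0.067 for oxidative phosphorylation, and -0.14 for interferon and antigen presentation, -0.12 for Kupffer cell markers, -0.11 for sinusoidal endothelium markers, -0.087 for glucocorticoid-responsive genes and -0.078 for PPARalpha targets. With an estimated correlation 0 of the 9 were called (smallest adjusted p = 0.615), and in the liver channel the ribosomal median was 0.024 (adjusted p = 0.780). Of 100 splits drawn within the slides, 13 gave at least 9 called lists (13 at the most in another split), so chance cannot be excluded. Neither the fit of the interaction nor these splits take up the sample numbers that CC and MM share. For features, 100 of 100 gave at least the real 0 (6 at the most), which a real count of 0 fixes in advance, so nothing was tested there.

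The log ratio differences between exposed and control rats were larger than those of other splits. Of 35 splits, 1, the real one, gave as many as 466 features in M minus C (1 at the most in another split), and 1 of 35 gave as many as 98 in MM minus CC (0 at the most in another split). Over these 35 splits chance can be excluded for the features of M minus C, but only 18 of them keep 2 arrays of each group in each slide row (0 features at the most in another), too few for a share under 0.05. It cannot be excluded for the lists of M minus C, where 20 of 35 splits gave at least 4 (12 at the most). For the lists of MM minus CC, 17 of 35 gave at least 5 (14 at the most). In MM minus CC, however, shared sample numbers were taken to pair the arrays, although same-numbered arrays also share the slide row. With the real split only 8 part all 4 pairs, too few for a share under 0.05. The 7 others gave 0 features and up to 14 lists, and the 24 that part 2 pairs and the 3 that part none gave 0 features too.

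A reference channel that differs between the slides may account for part of these calls. The median share in the reference was 66.4% in M minus C and 85.8% in MM minus CC. It is taken of the changes of the separately normalized channels and not of the log ratio. The features were selected on the log ratio, of which the reference is a part, so a high share was favoured in advance. Without the share over all features, it cannot show how much of the calls the reference accounts for. The reference differed between slides in 6952 features, and 1 of 100 splits of the 16 arrays, the real one, gave as many (3796 at the most in another). Mixture exposure as a cause cannot be told apart from the slide, because each slide holds 1 exposure, and in the liver channel alone 1 feature passed in M minus C and 3 in MM minus CC. With the row as a block, the liver channel gave 89 (68 higher and 21 lower, 37 of them among the 466) and 46 (26 and 20, with 14 among the 98), and between slides 222 features differed in it (167 higher and 55 lower). The median absolute difference between slides was 0.072 log2 units in the liver channel and 0.090 in the reference. Called genes with no detected difference in the reference, such as Akr1c1, stay open to either.

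Between the slide rows 5025 features differed in the liver channel, and 1 of 100 redrawings of the row labels within groups, the real one, gave as many (3976 at the most in another). A position effect acting on both channels alike is argued against by the reference channel, in which 1.40% of features differed between rows. The median absolute row effect of the added spike-in RNAs was 0.0154 log2 units (10 RNAs, median SE 0.0561), against 0.159 for the tested features. Both were measured on log ratios after loess, which removes labelling or hybridisation effects that act on all spots alike or by intensity. On such effects the test cannot decide. It argues only against what loess leaves of labelling or hybridisation of the liver sample, as far as that acts on the spike-ins too. Effects that depend on sequence or enter before the spike-ins were added stay open, as do the order of dissection and the litter, none of which the labels give per array. No biological explanation was tested.

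In MM minus M, 8 lists were called, and 6 of 35 splits gave at least as many (13 at the most in another), so chance cannot be excluded. Correlation between the genes of a list stays possible for these calls, as 0 of the 8 stayed with an estimated correlation. That estimate came from a fit without the slide row, and 42.5% of features differed between rows in the log ratio. It therefore cannot separate correlation between genes from the row. With the slide row as a block 6 of 8 stayed called, but each row holds as many arrays of both groups, so the block leaves the medians as they are and cannot speak to the row, contrary to what was set out beforehand. A shift that differs between the rows stays open (ribosomal median -0.0055 in the first and 0.18 in the second), as does cross-fostering itself. For features, 35 of 35 splits gave at least the real 0, which a real count of 0 fixes in advance. The highest other, 2829, came from the split that follows the slide row, which points to a structure of the arrays. With the row as a block the real split again gave 0 features.

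In CC minus C, 35 of 35 splits gave at least the real 0 features (1 at the most), which a real count of 0 fixes in advance. For lists, 30 of 35 gave at least 2 (15 at the most). In the mean of both contrasts, 100 of 100 drawn splits gave at least the real 0 features, again fixed in advance, with 3472 at the most in a split that lay close to the slide rows. For lists, 56 of 100 gave at least 4 (13 at the most). For the correlation of -0.188 between the contrasts, 691 of 1225 pairs of splits gave one at least as large in size, with 0.758 the largest. Chance cannot be excluded for these lists or for this correlation, and the counts of 0 features left nothing to test.

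Single arrays lay apart from the other 3 of their group for 49 of 844 sets of a named gene and a group, where chance alone gives about 42.2. The values given here are differences in log2 ratio from the mean of the other 3 arrays. C replicate 11, with 9 of them, differed by -1.73 for Tat, 0.59 for Apoc3, 0.57 for Akr1c1, -0.46 for Slc39a7, 0.43 for Cox5b, 0.37 for Aqp1, -0.36 for Irf9, -0.33 for Syngr2 and 0.25 for Apoa1. M replicate 8 differed by 0.95 for Fgl1, 0.73 for Cpt1a, -0.31 for Mcm3, -0.18 for Mcm4, 0.17 for Hadhb, -0.079 for Rpl28 and 0.036 for Rpl14. C replicate 12 differed by 0.58 for Agxt, 0.30 for Eng and -0.17 for Bhmt, C replicate 10 by -0.71 for Acot4 and 0.24 for Fgl1, and C replicate 9 by 0.25 for Akr1c2.

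Among fostered controls, CC replicate 2 differed by -2.24 for Cyp2c12, -0.38 for Cyp4a3 and -0.24 for Fbp1, CC replicate 3 by -0.57 for Cidec, 0.37 for Hadha and 0.36 for Ahsp, CC replicate 4 by 0.22 for Acaa2 and 0.13 for Syngr2, and CC replicate 1 by -0.58 for Rnf8. In the exposed groups, MM replicate 3 differed by 0.68 for Obp3, -0.54 for Slc25a1, 0.46 for Canx and 0.21 for Hsp90ab1, and MM replicate 4 by -1.61 for Dbp, 0.48 for Eif2ak2, 0.41 for Rhbg and 0.30 for Olr59. MM replicate 2 differed by -0.28 for Insr and -0.14 for Sparc, and MM replicate 1 by -0.064 for Krt8. M replicate 5 differed by 0.48 for Mvd, -0.35 for Zfp24 and 0.24 for E2f1, M replicate 7 by -0.27 for Aif1 and 0.13 for Cox8a, and M replicate 6 by 0.22 for Orm1.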

How the results depend on the processing

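Fits with the slide column as a block, within a slide row, without the first slide column, or of the liver channel with the row as a block were chosen after seeing the data, as were, for lists, the liver channel, the row block and the replicate block, and the row block for the correlation between contrasts. The 4 counts of 0 features in the fostering contrasts stayed at 0 in every setting that gave a value, except 1 in CC minus C with the scanner's log ratio. The 466 features of M minus C became 1364 with the scanner's log ratio, 1 in the liver channel, 268 with only the compared groups, 887 with array weights, 1202 with the row block, 191 with a fold of at least 1.5, 777 at an adjusted p under 0.1, 96 with the column block, 184 in the first row, 4 in the second, 253 without the first column and 89 in the liver channel with the row block (68 higher and 21 lower). In the same order, the 98 of MM minus CC became 486, 3, 14, 176, 421, 52, 164, 5, 65, 1, 25 and 46 (26 higher and 20 lower). Leaving out 1 array gave 213 to 450 and 31 to 101. The rows and the fits of fewer groups rest on fewer arrays, and the cause of the other changes was not tested.

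With the sample number as a replicate block, MM minus CC gave 131 features, 20 higher and 111 lower, with 3 residual degrees of freedom, and 61 of the 98 were among them. Of named genes and lists, calls were lost for Prima1 (adjusted p = 0.0641), Dapk3 (0.0763), Mtnr1a (0.0687), Krt8 (0.0639) and the immediate early genes (0.0502), and gained for Acot4 (0.0454). It changed no other call among the 57 other named genes and 4 other lists.

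Except without 1 array, counts of lists are followed by how many of the lists called as reported were among them, where that is fewer than either count. The estimated correlation left 0 called in each comparison, and fry gave 0 in the fostering contrasts and 1 in MM minus CC. The 2 lists of CC minus C became 1 with no filter, 4 in the first row (1 shared), 1 without the first column (0 shared) and 3 to 6 without 1 array (without CC replicate 1, 5, and 2, 4; without C replicate 10, 6, and 12, 5). The 8 of MM minus M became 3 with the scanner's log ratio, 5 in the liver channel (4 shared), 5 in the second row (3 shared), 4 without the first column and 5 to 11 without 1 array (5 each without MM replicate 2 or 3 and M replicate 7 or 8). The 9 of the interaction became 2 with the scanner's log ratio, 3 without the first column and 1 to 10 without 1 array (C replicate 9, 2, and 11, 1; CC replicate 4, 4; MM replicate 2, 2; M replicate 8, 5). The 4 of the mean contrast became 7 in the liver channel (3 shared), 9 in the first row (3 shared) and 0 to 7 without 1 array (CC replicate 1, 0, and 2 or 4, 7; MM replicate 1, 7; M replicate 6, 2). The 4 of M minus C became 1 with the scanner's log ratio (0 shared), 7 in the liver channel (1 shared, with 5 higher and 2 lower), 1 without the first column and 1 to 6 without 1 array (C replicate 11, 2; M replicate 7, 1, and 8, 2). The 5 of MM minus CC became 10 with no filter, 0 with the scanner's log ratio, 0 in the liver channel, 9 in the second row (4 shared) and 3 to 7 without 1 array (MM replicate 2, 3). The correlation of -0.188 between contrasts became -0.053 with the scanner's log ratio. The cause was not tested.

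Among called genes, directions reversed in the liver channel alone, with and without the row block. In M minus C they were Hsp90ab1 (0.15), Mbd3 (-0.0092), Fbp1 (0.040) and Apoa2 (0.050). In MM minus CC they were Krt8 (-0.0087), H1f4 (0.074), Hsp90ab1 (0.40) and Hadha (0.056). The liver channel setting leaves out the reference and also replaces loess within arrays by quantile normalization between arrays, and which of these matters was not tested. List medians or their test reversed for hepatocyte markers in MM minus M (-0.095) and M minus C (0.036), cell cycle in the mean contrast (-0.0044) and male-biased genes in MM minus CC (0.045, all liver channel), ribosomal proteins in MM minus M (-0.0055) and in the interaction (-0.083), cell cycle in MM minus M (-0.015) and interferon genes in M minus C (-0.031, all first row), fatty acid synthesis in the mean contrast (0.042) and immediate early genes in MM minus CC (-0.057, both second row). Of 6396 values of named genes, 5639 counted as unchanged, 364 lost the call, 59 gained it, 318 moved and 16 reversed. For a called gene, unchanged means that direction and call were kept, and only called genes could count as reversed. For an uncalled gene it means no call and a shift under its SD within groups, whatever the sign. The 6396 include 363 values with average intensity quantile-normalized and 363 with all probes, where the same probe was read. Of 293 values of lists, 131 kept direction and call, 152 lost the call and 10 reversed. Quantile normalization of average intensity leaves log ratios as they are and so tests nothing, and the fit of the compared groups alone gives no value for the interaction or the mean. Signal over background limits what can be seen of dim genes, and as few as 10625 of 30367 probes on an array were well above background in liver.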

Other observations

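The list of called genes without a detected reference difference, the most variable genes, the within-group shuffle and the tests of Dbp with Per2 and of Cyp2c12 with Cyp2c11 were chosen after results were seen, and the other 3 gene pairs given here before.

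Of the 466 features called in M minus C, 31 showed no detected difference of the reference between slides, 12 higher and 19 lower in M, and 22 of them had a symbol. Among the lower ones were the aldo-keto reductase genes Akr1c2 (-1.77 ± 0.41, SE) and Akr1c1 (-0.92 ± 0.14), the globin genes Hbb-b1 (-0.91 ± 0.21) and Hbe2 (-0.86 ± 0.22), and Retn, which encodes resistin (-0.35 ± 0.09). Apoe was also lower (-0.36 ± 0.09), but its liver channel differed by -0.01 only. Among the higher ones were Shisa5 (0.51 ± 0.11), Bri3 (0.44 ± 0.10), the disulfide isomerase gene Pdia6 (0.36 ± 0.08) and the iron-sulfur scaffold gene Iscu (0.36 ± 0.09). In MM minus CC there were 4 such features, 1 with a symbol, Ednra (-0.78 ± 0.14, adjusted p = 0.0144). An undetected difference does not show that the reference was equal, and within each contrast slide and exposure cannot be told apart. An effect of slide or exposure that is the same with and without fostering cancels in the interaction. There Akr1c1 stood at 0.90, Akr1c2 at 1.85 and Hbb-b1 at 0.85, opposite in sign to their falls in M minus C. No feature passed there (smallest limma adjusted p = 0.854), so a slide effect is not excluded. The set as a whole was not compared in this way.

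Pools of the same group varied most, among genes with a symbol, in Pnpla5, a lipase gene (SD within groups 1.54 log2 units), Cfap95 (1.34), the plasma kallikrein gene Klkb1 (1.28), the sulfotransferase gene Sult2a6 (1.17) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.05), against a median of 0.18 over all 11084 features. The nuclear receptor gene Nr0b2, which represses Cyp7a1, had an SD of 0.91, Dbp of 0.87, Bcl6 of 0.86 and the female-biased Cyp2c12 of 0.81. For Crym the SD fell from 0.90 to 0.55 once the slide row was removed, and for Dbp it was 0.87 before and after.

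Pools may differ in clock phase. The clock output gene Dbp and Bmal1, which peak at opposite times of day, correlated at -0.848 over the 16 arrays after group means were removed (permutation p = 0.00029, adjusted over 6 pairs 0.00174; Spearman -0.782, permutation p = 0.00208, adjusted 0.0125). The correlation was -0.823 and -0.853 in the first and second slide rows, -0.812 and -0.895 in slides 1 and 2, and -0.847 without the arrays farthest in Dbp. Dbp and Per2 correlated at 0.722 (permutation p = 0.00622, adjusted 0.0187; Spearman 0.688, permutation p = 0.00938, adjusted 0.0281), at 0.747 and 0.873 within the rows, 0.704 and 0.744 within the slides and 0.790 without the same arrays. Both are consistent with the hypothesis that the time of dissection varied between pools, which the labels do not give.

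Other pairs showed no relation past the threshold when arrays were shuffled within their groups. For Cyp7a1 and Cyp8b1, both of bile acid synthesis, r was 0.563 (permutation p = 0.0742, adjusted 0.111; Spearman 0.450, permutation p = 0.173) and 0.374 without the arrays farthest in Cyp7a1, with 0.481 and 0.689 within the rows. For the fasting-induced Pck1 and Igfbp1, r was 0.605 (permutation p = 0.0586, adjusted 0.111; Spearman 0.515, permutation p = 0.104) and 0.588 without the arrays farthest in Pck1, with 0.325 and 0.891 within the rows. A shuffle over all 16 arrays was run first, and under it both passed (adjusted permutation p = 0.035 and 0.0248). The within-group shuffle replaced it after those results had been seen, because values with their group means removed can be exchanged only within a group, so whether these pairs are related depends on that choice and stays open. The other 3 pairs given here fell on the same side of the threshold under both shuffles.

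For the female-biased Cyp2c12 and the male-specific Cyp2c11, r was -0.0589 (permutation p = 0.763, adjusted 0.763; Spearman 0.05, permutation p = 0.859), and -0.02 without the arrays farthest in Cyp2c12, with 0.278 and 0.112 within the rows.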
